A study of Mus musculus with 6 samples.

How the data were processed

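Total RNA from whole kidneys of 3 control and 3 Nampt conditional knockout mice was labelled with Cy3 and hybridised to SurePrint G3 Mouse GE 8x60K arrays, 1 array per animal, per the labels. Groups and replicate numbers were taken from the labels alone. The scanner files hold spot intensity on a linear scale, which the authors extracted with Agilent Feature Extraction 10.7.1.1, per the file headers and the submitters' processing notes. The processed intensity is background-subtracted and detrended within each array, per the file headers, and is not scaled between arrays. The other columns used are 0 or 1 flags per spot (well above background, saturated, outlier), as deposited by the authors. The authors' deposited value table holds a linear ratio. It was set against each array's processed signal for the 13934 to 13936 probes per array with a ratio above 1, and dimmer probes were not compared. At least 99.99% of the compared probes had a value equal, within 1%, to the signal divided by a constant of that array. The 75th percentile was at about 1.00 and column medians lay between 0.075 and 0.084, so neither a log scale nor centring of genes was found. The software that made that table is not given in the sources used here.

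For the main analysis, log2 of the processed signal was taken, outlier spots were left out (92 to 151 per array), spots of 1 probe were averaged and each array's 75th percentile over 55681 probes was subtracted. Probes well above background on all arrays of at least 1 group were kept, 32948 in all. Probe accessions were matched without versions to the RefSeq table of mouse assembly GRCm38.p6, which named 28026 probes for 21154 genes and left 27655 probes without a name. That assembly differs from mm9, the build of the array's probe positions per the file headers, so the table was used only for names and for which genes share a chromosome or neighbour each other. For the 5681 genes with more than 1 probe, the probe with the highest mean was used among those kept. This left 15309 genes.

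Knockout was compared with control by limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the group as the only term and Benjamini-Hochberg adjustment at 0.05. Scripts in Python 3.11.15 with pandas 2.3.3 read the files, and matplotlib 3.10.9 drew the plots. With 3 animals against 3, an exact two-sided permutation test of a single gene cannot go below p = 0.1, so limma's moderated test is the one given. A gene not well above background on any array of a group has only a bound there, given as at least N-fold, from the mean of the detected group against the dim group's mean of, per array, the higher of the gene's own signal and the lowest signal detected above background. Before the data were examined, 22 pathway and 18 cell type marker lists were fixed, holding 931 names, of which 2 had no match. Each was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 40 lists, and again with an estimated correlation and with fry. The adjustment over the list alone uses only that list's p-values.

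The rule for named genes was also fixed before the data were examined. It takes Nampt, then the 10 largest rises and the 10 largest falls among genes that passed and whose groups did not overlap, then up to 4 members of smallest p of each list described, with Sirt1, Sirt6, Col4a1, Col4a2, Col4a3, Timp1, Mmp2, Mmp9 and Mmp14 whatever their p. The lists described are those called and those on NAD metabolism, the proximal tubule, neutrophils and adipocytes. Some genes that the rule takes, and the tests of explanations made on them, are not reported here. A further 6 genes that rose are named because they passed the test, and were chosen after their values were seen.

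Alternatives were quantile normalisation, scaling by the median of detected probes, normexp with an offset of 50 and quantile normalisation, the authors' deposited ratios, no filter or a filter on all 6 arrays, the mean of a gene's probes, probes in place of genes, a trended and robust variance, array weights, a 1.5-fold minimum, the replicate number as a block, slide row as a block and leaving out each array. The normexp alternative was planned on mean spot signals and was run on median spot signals, the column in the files. On simulated data for this comparison (15307 genes, 200 changed, 20 runs), 63.8% of 1.5-fold, 81.3% of 2-fold and 95.7% of 4-fold changes were recovered. Of the calls, 5.85% were false. The simulated genes were independent, which real genes are not. The changes were placed on genes at random, whatever their spread between animals, so the shares recovered may not hold for genes that vary more. The arrays share 1 slide and 1 scan, so slide row was the only batch tested.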

Results

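Gene expression was measured in whole kidneys of male C57BL/6J mice, 3 controls and 3 animals labelled as Nampt conditional knockouts, with 1 single-colour Agilent microarray per animal. Nampt encodes the rate-limiting enzyme of the NAD salvage pathway. The series title places the knockout in the renal proximal tubules and names Sirt6, an NAD-dependent deacetylase, and extracellular matrix deposition. The comparison of knockout with control kidneys asks which transcripts differ when Nampt is deleted there. Between 57.3% and 63.3% of the spots on an array were well above background, and no spot was saturated. Arrays correlated pairwise with Pearson r between 0.994 and 0.997 across 30025 probes detected on all arrays, a correlation across probes, which are not independent replicates. All 6 arrays lay on 1 slide, with the 3 controls and knockout 1 in its first row and knockouts 2 and 3 in its second. The lowest signal detected above background was 18.5 to 20.9 units on the arrays of the first row and 29.6 and 32.2 units on those of the second. The replicates are separate mice as the labels number them, so p-values of single genes measure the spread between these animals. The number of animals limits the precision. Camera's p-values at its preset correlation compare a list's genes with the other genes and do not measure the spread between animals alone.

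Nampt fell in the knockout kidneys, by 1.06 on the log2 scale ± 0.10 (SE; limma adjusted p = 0.0431). Its normalised log2 signal was 2.67 ± 0.09 (SD, n = 3) in the controls and 1.61 ± 0.17 (SD, n = 3) in the knockouts. The controls lay at 2.775, 2.591 and 2.646, and the knockouts at 1.804, 1.502 and 1.531. The transcript stayed well above background on all 6 arrays, and the lowest control lay above the highest knockout. The sources used here do not give the deleted exons, so whether the probe lies inside the deletion is not known. With slide row as a block, which rests on knockout 1 alone against the controls beside it, Nampt was at -0.87 (adjusted p = 0.0733). Over 17 other settings the adjusted p ran from 0.00880 to 0.184 and passed 0.05 in 9 of them, and the log2 difference ran from -1.15 to -0.87.

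The genes that rose in the knockout kidneys included Mmrn1, which encodes the platelet and endothelial protein multimerin. Mmrn1 was not well above background on any control array and was at least 3.35-fold higher in the knockouts (limma adjusted p = 0.00507). Skint3 rose by 1.29 ± 0.13 (log2, SE) and Fmn1, the actin regulator formin, by 1.18 ± 0.12. Cirbp, a cold-inducible RNA-binding protein, rose by 1.05 ± 0.10. Greb1 rose by 0.95, Dgkg, a diacylglycerol kinase, by 0.91, Lpar2, a lysophosphatidic acid receptor, by 0.85, and Grifin and Sntg2 by 0.77 each, with adjusted p between 0.0314 and 0.0458 for these genes from Skint3 on. With normexp and quantile normalisation Skint3 was at 0.46 (adjusted p = 0.153), Lpar2 at 0.49 (0.0724) and Grifin at 0.33 (0.0631), and these calls were lost. A further 6 genes that rose were Bach2, Rad54l, Txnip, Siglec1, Hbegf and, by the probe used, Dtd2, another of whose 3 probes was at -1.63.

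Among the genes that fell, Wfdc21 was well above background in all 3 controls and in no knockout, at least 1.45-fold lower (limma adjusted p = 0.0217); with normexp and quantile normalisation it was at -0.48 and the call was lost (adjusted p = 0.0611). Rnf24, on the fixed list of markers of the straight segment of the proximal tubule, fell by 1.04 ± 0.10 (SE; adjusted p = 0.0431). Slitrk6 fell by 0.95, the mitochondrial nucleotide kinase gene Cmpk2 by 0.94 and Plek2 by 0.89. The size for Cmpk2 depended on the probe, with its other probe at -1.92. Slc22a26, of the organic anion transporter family, fell by 0.87, and Slc38a6 by 0.55. The adjusted p of these genes lay between 0.00823 and 0.0458.

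**Figure D1:**
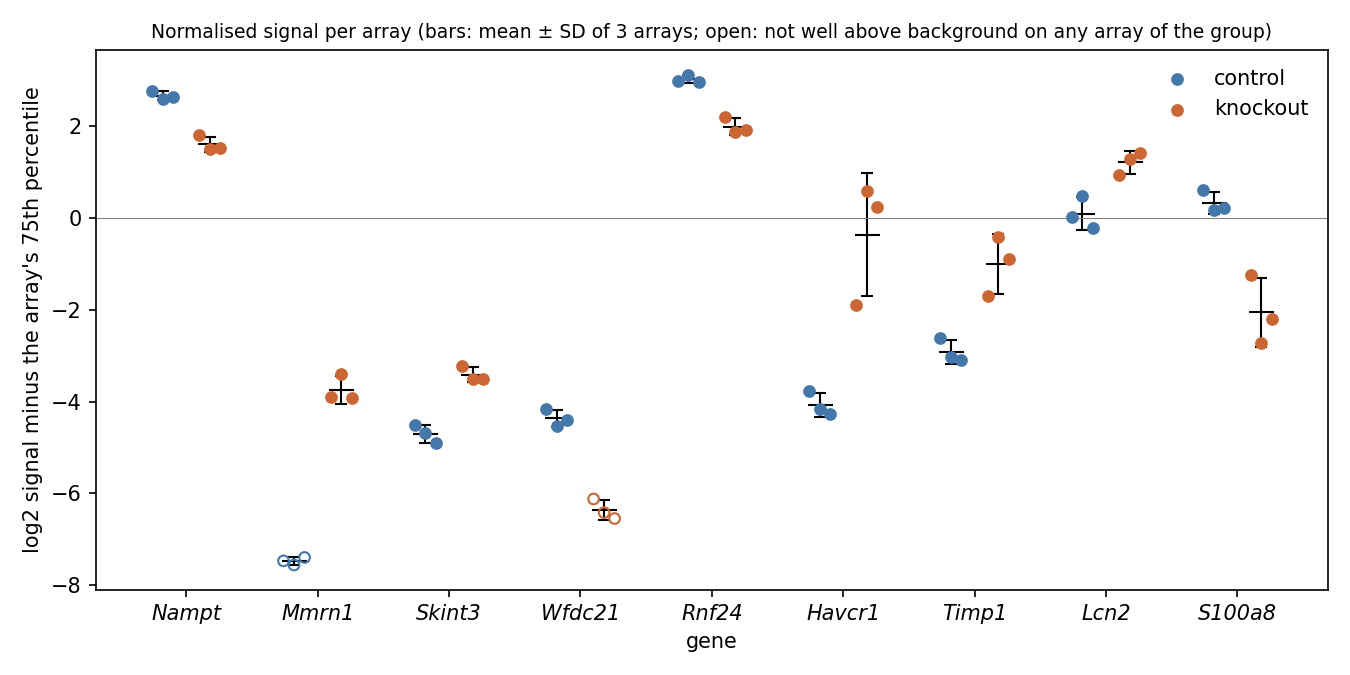
Normalised log2 signal of 9 named genes on each array (vertical axis, log2 signal minus the array's 75th percentile), with controls in blue, knockouts in orange and bars at the mean ± SD of 3 arrays. Nampt and Rnf24 lay lower in all knockouts and Mmrn1 and Skint3 higher; Havcr1, Timp1, Lcn2 and S100a8 also separated the groups without passing the test over all genes.

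In all, 26 of 15309 genes tested passed a Benjamini-Hochberg adjusted p of 0.05 by limma, 16 higher and 10 lower, and 24 of them differed at least 1.5-fold. At an unadjusted p under 0.05 there were 1962 genes, 1024 higher and 938 lower, where chance gives 765 on average. Genes are not independent, and other divisions of the 6 arrays into 3 and 3 gave from 205 to 1131 such genes. The groups did not overlap in 19.5% of genes, where chance gives 10%. With quantile normalisation 5 genes were higher and 6 lower, and with normexp and quantile normalisation 13 and 14. With slide row as a block 5 were higher and 11 lower, and 2 of the 26 kept their call. Without control 2 or control 3 no gene passed (1445 and 1563 at an unadjusted p under 0.05), without knockout 2 or knockout 3 a single gene did, and without knockout 1 there were 59 higher and 36 lower. Of the 26 genes, 8 lie on chromosome 12 in the GRCm38.p6 RefSeq table. They include Nampt, Greb1, Sntg2, Dtd2, Cmpk2, Plek2 and Slc38a6. Without that chromosome, an alternative chosen after seeing the data, 1 gene was higher and 3 were lower. The differences of the 18 called genes on other chromosomes are unchanged by that removal. The Benjamini-Hochberg adjustment depends on the small p-values of the other genes. Of the 16 gene lists called by camera at its preset correlation, 0 kept their call with an estimated correlation, 7 with slide row as a block and 8 without control 3. The list medians of all 3 knockouts lay beyond those of all 3 controls in 4 of the 16, tubular injury, the p53 response, fatty acid oxidation and the unfolded protein response. For the unfolded protein response the margin was slight, with -0.0401 in knockout 3 and -0.0395 in control 2. The lists of NAD-consuming enzymes and of the straight proximal tubule, which were not called, separated as well.

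In the tubular injury list, Hbegf, a growth factor of the epidermal growth factor family, rose by 0.60 ± 0.06 (adjusted p = 0.0458). Havcr1, which encodes the injury marker KIM-1, was 3.71 ± 0.65 higher (adjusted p = 0.138), at -0.36 ± 1.35 (SD, n = 3) against -4.07 ± 0.26 (SD, n = 3) in the controls. Lcn2, which encodes the injury marker NGAL, was 1.12 ± 0.21 higher (adjusted p = 0.156), and the transcription factor gene Sox9 0.82 ± 0.17 higher. None of these 3 passed over all genes, although all 3 knockouts lay above all 3 controls for each of them. Of 27 measured members, 1 rose over all genes, and adjusted over the list alone 5 were higher and 1 lower. The list as a set was higher by camera (median 0.23; adjusted p = 0.000102), with adjusted p = 0.804 with an estimated correlation and 0.214 with slide row as a block.

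The matrix turnover list was led by Timp1, an inhibitor of matrix metalloproteinases, which was 1.91 ± 0.33 higher (adjusted p = 0.138). Its arrays averaged -2.92 ± 0.26 in the controls and -1.003 ± 0.65 in the knockouts (SD, n = 3 each). Adam17 was at 0.21 ± 0.06, while Mmp15 was at -0.40 ± 0.10, none passing over all genes. Over the list alone, 1 of 27 members was higher. The gelatinase gene Mmp2 was at 0.27 ± 0.34 and Mmp14 at 0.23 ± 0.23, both within the spread between animals and both below 0 with slide row as a block (-0.35 and -0.0091). Mmp9 was well above background on 1 control array and no knockout array and was not tested. As a set the list was higher by camera (median 0.16, adjusted p = 0.00588), with adjusted p = 0.804 with an estimated correlation and 0.163 with slide row as a block. Its call was also lost without control 3 and with no filter on dim probes.

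Type IV collagen genes of the basement membrane differed little. Col4a1 was at -0.04 ± 0.11 and Col4a2 at -0.03 ± 0.08, with signs that turned when control 1 was left out (0.06 and 0.03). Col4a3 was at 0.17 ± 0.06 (adjusted p = 0.351), and the laminin genes Lama3, Lama5 and Lamb2 at 0.64 ± 0.23, 0.20 ± 0.05 and 0.17 ± 0.07. None of the 26 measured members passed over all genes, and 0 did when adjusted over the list alone. The list had a median of 0.06 and was higher by camera (adjusted p = 0.0283), with adjusted p = 0.804 with an estimated correlation and 0.339 with slide row as a block. Its call was also lost without control 3, without knockout 2, without knockout 3, with array weights and with the mean of a gene's probes. The same held with no filter on dim probes and with the replicate number as a block. In the interstitial matrix and fibrosis list, Col8a1 was at 0.57 ± 0.19, Thbs2 at 0.49 ± 0.16, Lum at 0.49 ± 0.20 and Col5a2 at -0.52 ± 0.15, and 0 of 31 members passed over all genes or adjusted over the list alone. Its median was 0.15 (camera adjusted p = 0.0134; adjusted p = 0.893 with an estimated correlation; 0.480 with slide row as a block), while the 3 controls alone spanned list medians from -0.40 to 0.34 around their mean. Without control 3 the camera direction of this list turned (adjusted p = 0.881). Its call was also lost without knockout 2, with no filter on dim probes and with array weights.

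Macrophage and dendritic cell markers formed the list with the smallest p. The lysozyme genes Lyz1 and Lyz2 were 1.39 ± 0.30 and 1.37 ± 0.32 higher, the invariant chain gene Cd74 0.44 ± 0.10 and the macrophage growth factor receptor gene Csf1r 0.28 ± 0.06, none passing over all genes. Adjusted over the list alone, 13 of 24 members were higher and 0 lower. The median was 0.31 (camera adjusted p = 1.67e-09), with adjusted p = 0.804 with an estimated correlation and 1.42e-06 with slide row as a block. Against the control mean, the list's median was 0.28 in control 1, -0.09 in control 2 and -0.14 in control 3, and 0.28, 0.44 and 0.25 in the knockouts, so control 1 lay within the knockout range. In the list of inflammatory cytokines and NF-kB targets, the chemokine gene Ccl8 was 1.59 ± 0.30 higher, Tlr2 at 0.47 ± 0.14 and Tnfaip3 at 0.41 ± 0.11, while Il1b was at -0.84 ± 0.21. Over the list alone 1 of 26 was higher, and the set had a median of 0.13 (camera adjusted p = 0.00416; adjusted p = 0.804 with an estimated correlation; 0.0226 with slide row as a block). Its median was 0.23 in control 1, above the 0.17, 0.12 and 0.16 of the knockouts, and the call was lost without control 3. With no filter on dim probes this call was also lost, as was that of the T and NK cell list. The T and NK cell list had a median of 0.36 with 0 of 18 members passing over the list alone (camera adjusted p = 0.00588; adjusted p = 0.804 with an estimated correlation; 0.319 with slide row as a block), and its call was also lost without control 3; control 1 lay at 0.29, above knockout 1 at 0.18; Cd2 was at 0.58 ± 0.23, Cd3g at 0.50 ± 0.21, Cd28 at 0.34 ± 0.14 and Gzma at -0.41 ± 0.10.

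Neutrophil markers did not move together. S100a8 and S100a9, the calprotectin subunits, were at -2.39 ± 0.37 and -2.34 ± 0.39 and Retnlg at -1.16 ± 0.31, while Lcn2 was higher as above. Over the list alone 1 of 9 members was higher and 3 were lower, and the list was not called (camera adjusted p = 0.644). Haemoglobin genes of the erythroid list did not pass over all genes (adjusted p from 0.236 to 0.428), with Hbb-b1 at -0.76 ± 0.22, Hbb-b2 at -0.68 ± 0.17, Hbb-bt at -0.77 ± 0.32 and Hba-a1 at -0.69 ± 0.31; the groups overlapped for Hbb-bt and Hba-a1, and 0 of 9 members passed over the list alone. The erythroid median was -0.02 in knockout 1, -0.77 in knockout 2 and -0.91 in knockout 3 (camera adjusted p = 0.0277 for the 3 together; adjusted p = 0.804 with an estimated correlation; 0.752 with slide row as a block), and Hba-a1 turned to 0.02 with that block. Adipocyte markers were not called (median -0.88; camera adjusted p = 0.0554; 0.0454 with slide row as a block, which would call them) and lay at -1.45, -1.83 and 0.53 in knockouts 1, 2 and 3; Retn was at -1.64 ± 0.47, Car3 at -0.99 ± 0.41, Pck1 at -0.11 ± 0.06 and Lipe at 0.58 ± 0.32.

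Among stress and growth programmes, the list of the p53 response and senescence was higher. Tnfrsf10b was at 0.28 ± 0.05, Bbc3, which encodes the pro-apoptotic protein PUMA, at 0.26 ± 0.05, Trp53inp1 at 0.29 ± 0.08 and Pmaip1 at 0.29 ± 0.08, none passing over all genes. Over the list alone, 2 of 25 were higher, and all 3 knockouts had a higher list median than every control (median 0.13; camera adjusted p = 3.16e-05; adjusted p = 0.804 with an estimated correlation; 0.00973 with slide row as a block). In the cell cycle list, Nusap1 was at 0.48 ± 0.06 (adjusted p = 0.0696), Rrm2 at 0.45 ± 0.08, Ccne1 at 0.35 ± 0.15 and Mcm7 at 0.17 ± 0.05, and 2 of 32 were higher over the list alone. Its median was 0.17 (camera adjusted p = 0.000111; adjusted p = 0.804 with an estimated correlation), with 0.21 in control 1 and -0.02, 0.35 and 0.24 in the knockouts, and its direction turned with slide row as a block (adjusted p = 0.903). Immediate early and heat shock genes had a median of 0.10 (camera adjusted p = 0.0495). The adjusted p was 0.804 with an estimated correlation and 0.480 with slide row as a block. This call was also lost with quantile normalisation, with or without normexp, with no filter or a filter on all 6 arrays, and with the mean of a gene's probes. It was lost without the chromosome of Nampt as well, and held in 2 of the 6 fits that left out 1 array. Nr4a2 was at 0.50 ± 0.14, Dusp6 at 0.39 ± 0.09, Atf3 at 0.38 ± 0.10 and Hsph1 at -0.25 ± 0.06, and 0 of 25 passed over the list alone. Podocyte markers had a median of 0.06 (camera adjusted p = 0.0378; adjusted p = 0.804 with an estimated correlation; 0.752 with slide row as a block); Cldn1, more widely an epithelial tight junction gene, was at 0.66 ± 0.07 (adjusted p = 0.0555) and was the 1 of 16 that was higher over the list alone, while Ptpro, Clic3 and Cdkn1c were at 0.21 ± 0.10, 0.21 ± 0.12 and 0.19 ± 0.12. Cdkn1c turned to -0.08 with slide row as a block. The podocyte call was also lost without control 1, without control 2, without knockout 2, with no filter on dim probes and with the mean of a gene's probes.

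In the cholesterol synthesis list, Cyp51 was at -0.26 ± 0.06 and Hsd17b7 at -0.20 ± 0.06. Of 24 members, 2 were lower adjusted over the list alone (median -0.12; camera adjusted p = 0.000111; adjusted p = 0.804 with an estimated correlation; 0.00184 with slide row as a block). In the list of fatty acid oxidation and PPAR alpha targets, Cyp4a10, a fatty acid hydroxylase, was at -0.60 ± 0.12, the peroxisomal Ehhadh at -0.46 ± 0.09 and Acadm at -0.16 ± 0.05, while Ppara itself was at 0.30 ± 0.09. None of 36 passed over all genes and 2 were lower over the list alone (median -0.12; camera adjusted p = 0.000173; adjusted p = 0.804 with an estimated correlation; 0.00990 with slide row as a block). In the oxidative phosphorylation list 41 of 44 were negative, with a median of -0.05 (camera adjusted p = 0.0107; adjusted p = 0.908 with an estimated correlation; 0.0457 with slide row as a block). Its median was -0.06, -0.04 and 0.11 in controls 1, 2 and 3 and -0.07, -0.04 and -0.05 in the knockouts, so that control 3 alone lay apart, and the call was lost without control 3, without knockout 1, with normexp and quantile normalisation and with array weights. Ndufs4 was at -0.12 ± 0.05, Ndufa2 at -0.11 ± 0.06, Ndufb8 at -0.11 ± 0.07 and Ndufs3 at -0.10 ± 0.06, and 0 passed over the list alone. In the unfolded protein and integrated stress response list, Xbp1 was at -0.52 ± 0.07 (adjusted p = 0.0877), Manf at -0.59 ± 0.13 and Dnajb9 at -0.33 ± 0.07, while Atf3 was higher as above, and 3 of 30 were lower over the list alone. Its median was -0.08 (camera adjusted p = 0.0106; adjusted p = 0.877 with an estimated correlation; 2.12e-08 with slide row as a block), with -0.28 in knockout 1 and -0.04 in each of the others, and the call was lost without control 3, without knockout 1 and with array weights.

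Other genes of NAD metabolism differed less than Nampt. Nmrk1, a nicotinamide riboside kinase, was at -0.34 ± 0.09, Nmnat1 at -0.14 ± 0.06 and Kmo at 0.13 ± 0.05, and Nampt was the 1 of 17 members of the NAD synthesis list to pass, over all genes or adjusted over the list alone (camera adjusted p = 0.765). Sirt6 was at -0.11 ± 0.04 (adjusted p = 0.401) and Sirt1 at 0.07 ± 0.05 (adjusted p = 0.644). Of the other NAD-consuming enzymes, Parp10 was at 0.32 ± 0.07, Parp2 at 0.22 ± 0.06 and Sirt2 at -0.13 ± 0.05, and 0 of 22 passed over the list alone (camera adjusted p = 0.211). Proximal tubule markers were not shifted as sets, with medians of -0.02 over 29 members for the convoluted and 0.03 over 20 for the straight segment (camera adjusted p = 0.671 and 0.847). Among them Cyp27b1, the vitamin D 1-alpha-hydroxylase, was at -1.48 ± 0.47 (adjusted p = 0.299). Its signal was -0.07 in knockout 1, within the controls' range of -0.10 to 0.75. Knockouts 2 and 3, both on the second slide row, lay at -1.64 and -1.56. Hnf4a was at -0.12 ± 0.06, Slc9a3 at 0.12 ± 0.06 (its other probe at -0.08), Slc22a19 at -0.29 ± 0.10, Cyp7b1 at 0.17 ± 0.05 and Slc16a9 at 0.10 ± 0.05.

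**Figure D2:**
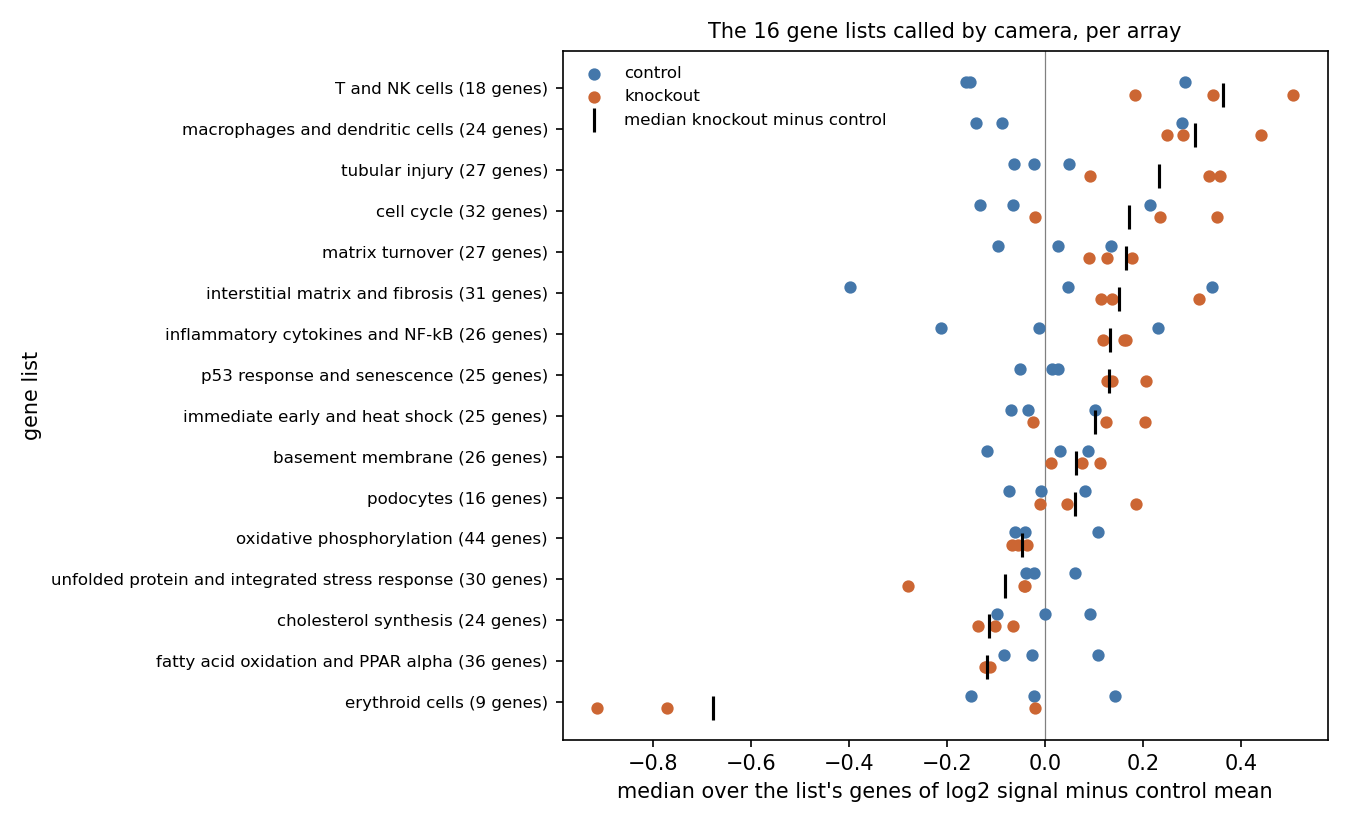
Median over each list's genes of the log2 signal minus the control mean (horizontal axis) on each array, controls in blue and knockouts in orange, for the 16 gene lists called by camera, with a black mark at the median difference of the knockout and control means. Knockouts and controls separated for the p53 list, while control 1 lay within the knockout range for the macrophage list.

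In all, camera called 16 of 40 gene lists, 11 higher and 5 lower, and 0 with an estimated correlation or by fry, which called 13 when change in either direction counted. With slide row as a block 7 of the 16 kept their call, and other divisions of the 6 arrays into 3 and 3 called up to 21 lists. With an estimated correlation the adjusted p was at least 0.804 for every list. The 24 lists not called included the tricarboxylic acid cycle (camera adjusted p = 0.229), glycolysis and hypoxia (0.599), gluconeogenesis and amino acid catabolism (0.662), fatty acid and triglyceride synthesis (0.662), NRF2 and glutathione (0.644), the interferon response (0.671), the circadian clock (0.923) and androgen-dependent genes (0.847). Among cell types, the thick ascending limb and the distal convoluted and connecting tubule (0.0799 each), the thin limb (0.703), principal cells (0.117), intercalated cells (0.240), endothelium (0.703), stroma and smooth muscle (0.211), B and plasma cells (0.229), adrenal gland (0.671) and urothelium (0.671) were not called either. In 10 lists, all among those not called, the median, the mean and the camera direction differed in sign.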

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

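Among 12758 probes without a gene name here, which the comparison of genes does not use, 1 was higher in the knockout kidneys and 6 were lower at an adjusted p under 0.05 over all probes. The higher one, a signal in data outside the named genes and above its level in the controls, was at 0.61 ± 0.05 (log2, SE, n = 3 each; limma adjusted p = 0.0326) and was well above background on all 6 arrays. No explanation was tested for it.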

How the results depend on the processing

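All 26 changed genes kept their direction in the alternatives that tested them, except 1 (Dtd2) with the mean of a gene's probes. The groups did not overlap for any of the 26. Leaving out 1 array, or slide row as a block, therefore could not turn the sign of the same probe. A trended variance and the replicate block leave the difference itself unchanged, so these settings did not test direction. The calls of the 26 genes held less well. Quantile normalisation gave 5 higher and 6 lower genes and Nampt at -1.04 (adjusted p = 0.0579). No filter on dim probes gave 64 higher, a trended and robust variance 27 higher and 30 lower, array weights 51 and 38, and probes in place of genes 9 and 17. Slide row as a block gave 5 higher genes, 8 lists and Nampt at -0.87 (adjusted p = 0.0733). Without the chromosome of Nampt, chosen after seeing the data, 1 gene was higher and 3 lower, with the differences of the remaining genes unchanged. The lists fell from 16 to 0 with an estimated correlation and to 0 by fry. Leaving out 1 array gave 0 to 59 higher genes, 0 to 36 lower genes, 10 to 17 lists and Nampt at -1.154 to -1.003 (adjusted p = 0.0138 to 0.184), and removed arrays also leave fewer degrees of freedom. The highest counts came without knockout 1 (59 and 36), and the lowest without control 2 or 3 (0 and 0).

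Signs turned for Col4a2 under normexp and quantile normalisation (0.011). With slide row as a block they turned for Cdkn1c (-0.079), Hba-a1 (0.019), Lipe (-0.13), Mmp14 (-0.0091), Mmp2 (-0.35) and the called cell cycle list (adjusted p = 0.903). Leaving out 1 array, Col4a1 ran from -0.151 to 0.0642 and Col4a2 from -0.103 to 0.0314, both highest without control 1, and the adjusted p of the interstitial matrix and fibrosis list from 1.15e-06 to 0.881, with its direction turned without control 3. The cause was not tested. With the replicate block, 0 genes were higher, 0 lower (1636 at an unadjusted p under 0.05) and Nampt was at -1.06 (adjusted p = 0.0891), with 16 lists. Deviations of same-numbered arrays correlated at 0.10, -0.10 and -0.03, and those of different-numbered arrays at -0.09 to 0.12. With 3 animals per group, this gives no sign of pairing by number and cannot exclude it. Over all settings, values of single genes and lists kept a call 430 times, lost one 223 times, gained one 36 times, stayed without one 1926 times and turned direction 57 times. Signal over background limits the dim genes, whose floor was higher on the second slide row.

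Of the 24 lists not called, 16 turned direction in at least 1 setting, never with a call there (adjusted p in brackets). They were NAD synthesis (0.893), circadian clock (0.938), convoluted proximal tubule (0.942) and adrenal gland (0.942) with quantile normalisation, and NAD synthesis (0.918) and circadian clock (0.838) with normexp. With no filter they were NRF2 (0.733), androgen-dependent genes (0.458), straight proximal tubule (0.453), thin limb (0.733) and urothelium (0.742). With array weights they were NAD synthesis (0.729), tricarboxylic acid cycle (0.981), fatty acid synthesis (0.807), convoluted proximal tubule (0.770), thin limb (0.534) and adrenal gland (0.848), and with the replicate block circadian clock (0.973) and thin limb (0.922). With slide row as a block they were interferon response (0.199), androgen-dependent genes (0.239), straight proximal tubule (0.985), intercalated cells (0.339) and urothelium (0.563), and without the chromosome of Nampt NAD synthesis (0.758) and straight proximal tubule (0.963). Leaving out 1 array, the adjusted p of lists that turned ran from 0.0206 to 0.923 for interferon response, 0.300 to 0.973 for circadian clock, 0.239 to 0.896 for androgen-dependent genes, 0.195 to 0.895 and 0.219 to 0.998 for the convoluted and straight proximal tubule, 0.116 to 0.988 for endothelium, 0.461 to 0.988 for NAD synthesis, 0.0566 to 0.686 for the tricarboxylic acid cycle, 0.0171 to 0.854 for gluconeogenesis, 0.0344 to 0.988 for fatty acid synthesis, 0.152 to 0.988 for thin limb, 0.0345 to 0.607 for stroma and 0.264 to 0.982 for urothelium. The cause was not tested.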

Other observations

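Of the tests below, those on the other divisions of the arrays by list, on the part of the chromosome nearest Nampt and on slide row for that chromosome were fixed before their results were seen, and the others after. Some genes stood apart in knockout 1 alone and were chosen after their values were seen. Against the mean of the other 5 arrays, Spink6 was not well above background and at least 91.1-fold lower, and Rnase4 and Eddm3b, both on chromosome 14, were at 4.17 and 3.32 (log2). Ide, the insulin-degrading enzyme gene, and Fgfbp3, both on chromosome 19, were at -1.06 and -1.11. Of the 6 lower probes without a gene name, one placed by the files at mm9 chromosome 15, 66682293 to 66722977, was at least 8.00-fold lower, and one at chromosome 12, 53669892 to 53710742, was at -0.996.

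The 3 against 3 design allows 10 divisions of the arrays, too few for a share under 0.05. The real one gave 26 genes and the highest of the others 0 (1 of 10 gave as many as 26, the real one included). For lists the real one gave 16 and the highest of the others 21, and 5 of 10 gave at least 16, the real one included. The division of control 1, knockout 1 and knockout 2 from the rest gave the macrophage list a smaller adjusted p (2.44e-13) than the real one (1.67e-09). Camera's preset correlation treats such shared shifts of a list's genes as evidence, so the list calls here may follow differences between single animals as well as the knockout.

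Changed genes were concentrated on chromosome 12, which holds Nampt: without Nampt, 7 of 25 lay there (28.0%) against 3.44% of tested genes (one-sided Fisher's exact p = 1.51e-05), and all 7 among the 263 of its 526 tested genes nearest Nampt. Among uncalled genes, 25.5% of those nearest had an unadjusted p under 0.05, against 16.7% of the rest of the chromosome and 12.4% elsewhere (one-sided Fisher's exact p = 1.30e-08 for the nearest genes against those elsewhere; genes are not independent). A linked segment from another strain, carried along with the modified allele, is a candidate explanation. Slide position is not excluded: with it as a block, 3 of the 26 genes of smallest p lay there, 11.5% (one-sided exact binomial p = 0.0586), and that fit rests on 1 knockout array. Sequence variants under single probes stay open too, since 3 of 4 called genes there with a further probe had probes of one sign, and Dtd2 did not.

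By camera at its preset correlation the macrophage and tubular injury lists were higher in the knockouts, while 0 of 24 and 1 of 27 members passed over all genes and both lists had an adjusted p of 0.804 with an estimated correlation. A lower share of proximal tubule RNA would raise markers of other cell types alike, but the median per array of 101 markers of 7 other types differed by -0.01 between the groups (95% confidence interval between animals -0.05 to 0.0197), below the medians of 0.31 and 0.23 of the macrophage and injury lists, and the highest median of the 7 types was 0.15. Slide position is not excluded for the injury list, whose median per array was 0.27 ± 0.09 higher without slide row as a term and 0.10 ± 0.05 with it (SE; 95% confidence intervals 0.02 to 0.53 and -0.07 to 0.28), since knockout 1, the only knockout in the row of the controls, lay below the others. For the macrophage list it cannot be told apart, with 0.31 ± 0.15 and 0.265 ± 0.235, and intervals of -0.10 to 0.71 and -0.48 to 1.012 that both include 0; with slide row as a block, camera at its preset correlation kept this list (adjusted p = 1.42e-06) and lost the injury list (0.214). More macrophages or more transcripts per macrophage remain possible as a response to the knockout, and control 1 lay as high as knockout 1 (0.28 each).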
